A study of Mus musculus with 4 samples.

How the data were processed

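Gene expression was measured on a single-colour Affymetrix mouse gene array in bone marrow-derived macrophages of C57BL/6N mice. Bone marrow cells were differentiated in 10 ng/mL M-CSF with harvest on day 9, and were polarised for 48 h with 10 ng/mL interferon-γ (M1) or 20 ng/mL interleukin-4 (M2), per the labels' protocols. Each phenotype received vehicle or 10 ng/mL interleukin-1α (IL-1α) for 24 h. Total RNA was amplified to sense-strand DNA, labelled with biotin and hybridised, 1 sample per array. The 4 groups (M1 vehicle, M1 IL-1α, M2 vehicle, M2 IL-1α) hold 1 array each, so no group has a replicate. Groups were taken from the source names.

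The deposited values are log2 signals per probe set that the authors obtained with RMA in Affymetrix Expression Console, per the submitters' processing notes. In general, RMA subtracts background, quantile-normalises probes across arrays and summarises each probe set. Such processing sets the arrays to a common distribution before deposit, removes any global difference in RNA output, and compresses differences among dim probe sets. Versions and settings were not given in the sources used here. No source states the log base. The values run from 3.09 to 14.47 with medians of 7.344 (M1 vehicle), 7.379 (M1 IL-1α), 7.348 (M2 vehicle) and 7.317 (M2 IL-1α), which is the log2 scale of RMA, not centred per gene. Detection calls and scanner files were not used here, and the number of arrays limits the precision.

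Of 35556 rows, 21789 carried 1 gene in GEO's platform annotation, 1621 carried several and 12146 carried none. Gene symbols were checked through their Entrez numbers against a RefSeq table of assembly GRCm38.p6, where 21698 of the 21789 matched. No coordinates are given, because the build behind the array annotation was not given in the sources used here. Rows with several genes or none were left out of the gene comparisons. The probe sets of a gene were averaged (999 of 19938 genes had more than 1). A floor was set at the median of all genes over the 4 arrays, a log2 signal of 7.617, and 10625 genes reached it on at least 1 array. Probe sets of near-identical families (Gbp, Ifi200, Ifit, eosinophil-associated ribonucleases) can cross-hybridise, so values within such families are uncertain by member.

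Each comparison is a difference of log2 values between 2 arrays, and the response difference is a contrast of all 4. A gene was counted as higher or lower when the difference reached 1 (2-fold) and at least 1 of the arrays compared reached the floor. These differences have no replicate check and no p-value. A single model gave tests: limma 3.58.1 (R 4.3.3; lmFit, then eBayes with a trend) with phenotype and treatment as additive terms, at a Benjamini-Hochberg threshold of 0.05. It leaves 1 residual degree of freedom per gene, plus 10.05 from the prior. It tests the M2 minus M1 difference common to both treatments, and the IL-1α effect common to both phenotypes, against the departure from additivity. That departure holds noise and any true difference in response. The labels do not say whether arrays came from separate cultures or animals. The p-values therefore rest only on that departure in these arrays, with variance borrowed across genes, and measure no spread between cultures or animals.

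Before the data were examined, 29 gene lists were fixed: pathways of macrophage polarisation, cytokine response and metabolism, and markers of other cell types. They held 482 symbols, of which 435 were measured by a probe set with 1 gene. The other 47, among them the receptor gene Il1r1, were not analysed here. The median difference of each list with at least 3 members at the floor was placed among 10000 random lists of equal size. These were matched on the mean level of the 4 arrays in 20 bins, not on the level in each phenotype. The resulting percentile describes these arrays and is not a test across samples, and list members vary together. None of the 9 mitochondrially encoded transcripts was measured, and none of the 4 erythroid markers measured reached the floor. Named genes followed a rule also fixed beforehand: the 10 highest and 10 lowest per main comparison (leaving out predicted genes, clones, small RNAs, olfactory and vomeronasal receptor genes and receptor segments), up to 4 members per list, 22 check genes (21 measured), and the 5 highest and 5 lowest per limma effect, with the same genes left out.

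The alternatives were a 1.5-fold threshold, no floor, a floor at the 75th percentile (9.635), loess centring of each array on the mean of the 4, a further quantile normalisation, the brightest probe set per gene, and eBayes without the trend. A robust eBayes fit was added after seeing the data. The steps were tested on simulated data for 10625 genes with noise estimated from the M1 pair. For the IL-1α response in M2, 67 of 67 genes changed 4-fold, 32 of 67 changed 2-fold and 0 of 66 changed 1.5-fold passed the 2-fold rule, with 0 of 9655 unchanged genes. limma called 66 of 66 genes changed 1.5-fold by IL-1α in both phenotypes and 65 of 66 changed 1.5-fold by phenotype, with 0 of 10025 unchanged genes in either. A simulated 2-fold change equals the threshold of the 2-fold rule, so noise decided which of those genes passed. The simulated noise was normal and came from the M1 pair alone, so these rates need not hold for the data. There, Malt1 with a common IL-1α effect of 0.57 was not called at the main floor. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.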

Results

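The series asked how differently M1 and M2 macrophages respond to IL-1α. M1 macrophages here are bone marrow-derived cells activated with interferon-γ, and M2 macrophages are the same kind of cells activated with interleukin-4. IL-1α is an inflammatory cytokine of the interleukin-1 family. The data were 4 arrays, 1 for each of M1 vehicle, M1 IL-1α, M2 vehicle and M2 IL-1α, so no value below has a standard deviation. Levels are RMA log2 signals and differences are in log2 units, unless a fold is stated. Across all probe sets, the arrays of the M1 pair correlated at r = 0.9969 and those of the M2 pair at 0.9958, whereas arrays of different phenotypes correlated at 0.9617 to 0.9658.

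The vehicle arrays were compared first, because they show the polarisation on which the responses were laid. Each phenotype carried its textbook markers. In M2, the eosinophil-associated ribonuclease Rnase2a was higher by 8.66, the resistin-like protein Retnla by 7.75, the chitinase-like protein Chil3 by 7.57, the arginine-degrading enzyme Arg1 by 5.72 (52.9-fold), the mannose receptor Mrc1 by 5.31 and the transcription factor Egr2 by 5.30. In M1, the interferon-induced GTPase Gbp4 was 177-fold higher, the chemokine Cxcl9 174-fold, Cxcl10 114-fold, the acute-phase gene Saa3 102-fold and the nitric oxide synthase Nos2 74.1-fold. In the phenotype with the lower signal, each of these genes except Mrc1 read under the floor of 7.617, a level not shown to be above background, so the sizes are uncertain. Of 10489 genes, 737 were at least 2-fold higher in M2 and 716 at least 2-fold lower.

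The limma additive model, which used the M1 and M2 arrays of both treatments, placed the phenotype effect far outside the departure from additivity. It called 3526 genes higher and 3113 lower in M2 among 10625, and 786 and 673 of these differed by at least 2-fold. The 5 largest effects upward were Rnase2a (8.58 ± 0.08 SE), Retnla, Chil3, Mgl2 and Arg1, with limma adjusted p from 6.61e-14 to 3.48e-13. Leaving out clones and predicted genes, the 5 largest downward were Gbp4 (-7.46 ± 0.08), Cxcl9, Ms4a4c, Saa3 and Iigp1, with limma adjusted p from 7.45e-14 to 1.45e-12. All 10 read under the floor on both arrays of the phenotype with the lower signal, so their sizes and order are uncertain. These p-values rest on 1 residual degree of freedom per gene plus 10.05 from the prior, which borrows variance across genes. They set the effect against the departure from additivity in these 4 arrays, not against a spread between replicates.

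The gene lists separated along the same axis. Of the 22 interferon-γ response and M1 markers at the floor, 21 were at least 2-fold lower in M2 than in M1 under vehicle (list median -2.99), and limma called 21 lower over all genes and 21 when adjusted over the list alone. All 21 type I interferon-stimulated genes were at least 2-fold lower in M2, with a median of -3.99 and examples in Ifit2 (-6.07), Ifit3 (-6.02) and Irf7 (-5.73). Among the 24 NF-κB target genes, 16 were lower and 1 was higher, with the prostaglandin synthase Ptgs2 (-6.29), Traf1 (-3.87), Ccrl2 (-3.25) and Vcam1 (-3.00) among them. Of 14 cytokine genes, 11 were lower in M2, including Il12b (-5.61), Il1b (-4.89), Il1a (-4.61) and Tnf (-3.12). Of 21 pattern recognition receptors, 11 were lower and 1 was higher, with Clec4e at -6.00 and Tlr9 at -3.90. The medians of these 5 lists lay below every one of 10000 random lists. MHC class I presentation genes had a median of -1.11, with Nlrc5 at -2.94 and Tap1 at -2.80. The MHC class II list had a median of -0.61 and its regulator Ciita differed by only -0.13. Ifit2, Ifit3, Ptgs2, Traf1, Vcam1, Il12b, Il1b, Il1a and Clec4e read under the floor in M2 with vehicle, so the sizes of their differences are uncertain.

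In the other direction, 21 of the 24 interleukin-4 response and M2 markers were at least 2-fold higher in M2 and 1 was lower (median 3.81), and limma called 22 higher and 2 lower, both over all genes and adjusted over the list alone. Of 16 cholesterol synthesis genes, 15 were at least 2-fold higher in M2 (median 1.82), among them Idi1 (3.40), Sqle (2.91), Cyp51 (2.69) and Hmgcs1 (2.65), and limma called all 16 higher on either adjustment. Of 24 cell cycle genes, 22 were at least 2-fold higher (median 1.59), among them the cyclins Ccna2 (10.0-fold) and Ccnb2 (9.0-fold), and limma called all 24 on either adjustment. These 3 medians lay above every random list. Lipid handling genes had a median of 0.83 (Scd1 3.87, Fabp4 2.85, Pparg 2.20), and matrix and protease genes of 0.80 with members on both sides (Mmp12 4.82, Fn1 4.70, Mmp14 -3.48). Glycolysis and hypoxia genes had a median of -0.58, with the glycolytic regulator Pfkfb3 at -3.17 and the lactate transporter Slc16a3 at -1.90. Oxidative phosphorylation genes lay within the range of random lists at a median of 0.15 (percentile 86.6), with 0 of 20 members past 2-fold. Small differences remained there: limma called 14 of the 20 higher in M2 and 2 lower, against 3526 higher and 3113 lower of all 10625 genes. Between the IL-1α arrays, the list median was 0.32 (percentile 98.4), outside the 95% band of random lists. Idi1, Ccna2, Ccnb2 and Scd1 in M1 and Mmp14 in M2 read under the floor with vehicle, so the sizes of their differences are uncertain.

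Markers of other cell types also differed between the phenotypes and stand beside these groups as measured. Osteoclast markers had a median of 1.76 in M2 against M1 (Dcstamp 4.60, Ctsk 3.25, Atp6v0d2 2.32), and neutrophil markers 1.12 (Ngp 2.52, S100a8 1.26). Dendritic cell markers had a median of -1.76 over the 5 at the floor (Clec9a -4.35, Xcr1 -1.96, Batf3 1.40, which the M2 marker list also holds), which became 0.22 over all 11 measured members when no floor was applied. The macrophage core list had a median of -0.05, although Aif1 was at -3.88 and Cd14 at -2.33. Stromal and endothelial markers lay within the random range at 0.24, as did the unfolded protein response (0.19) and the immediate early and heat shock genes (0.14). The chemokine list had a median of -0.34, the IL-1 family of -0.91, the eicosanoid list of -0.41 and the antioxidant and iron list of -0.48, each below percentile 1. The lymphocyte list had only Cd79b (0.40) and Cd4 (-0.10) at the floor, and the mast cell list only Hdc (-0.93). Dcstamp, Ctsk, Ngp and S100a8 in M1 and Clec9a, Xcr1, Aif1 and Hdc in M2 read under the floor with vehicle, so their sizes are uncertain too.

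**Figure D1:**
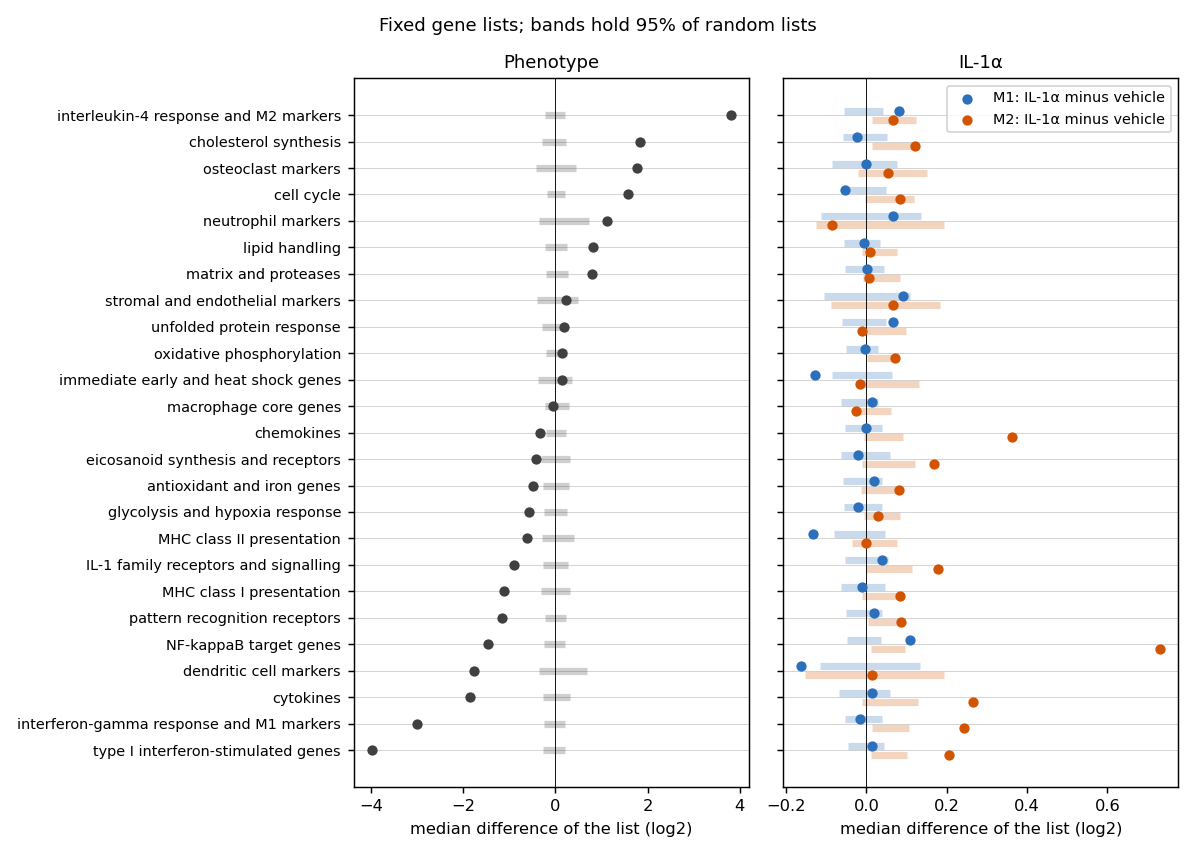
Median log2 difference of each fixed gene list (points) for M2 minus M1 under vehicle (left) and for IL-1α minus vehicle in M1 and in M2 (right); bands hold 95% of 10000 random lists matched on size and mean level. The horizontal scales differ: phenotype medians run from -3.99 to 3.81, and the largest IL-1α median is that of the NF-κB targets in M2, 0.73.

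The response of M1 macrophages to IL-1α was then examined. No gene of 10012 differed by 2-fold in either direction, and 2 genes were higher and 4 lower at 1.5-fold. The differences had a standard deviation over genes of 0.111. The largest among named genes were the respiratory chain subunit Uqcr11 (0.83), Cd300e (0.57), the purinergic receptor P2ry1 (0.54) and Sertad3 (0.47) upward, and Tbc1d7 (-0.65), the fatty acid desaturase Scd2 (-0.63) and Scnn1a (-0.53) downward, with P2ry1 under the floor with vehicle and Scnn1a with IL-1α. Among M1 markers, Nos2 read 13.00 with vehicle and 13.02 with IL-1α, Cxcl9 13.84 on both arrays and Il12b 11.78 on both. Nos2 and Cxcl9 lay within 2 log2 units of the top of the M1 vehicle array (14.4), where a ceiling could hide a rise. No replicate stands behind these differences. The 36 genes at least 2-fold higher in M2 with IL-1α had a median difference of 0.08 in M1, with a range of -0.17 to 0.39.

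Among the lists, the NF-κB targets stood apart in M1 with a small shift. Their median was 0.11, above every random list, and 20 of 24 members were above 0, led by the signalling paracaspase Malt1 (0.45), Nfkbiz (0.35) and Zc3h12a (0.34), none of them past 2-fold. Tlr2 was at 0.46, Il1b at 0.26 and Il1a at 0.23. MHC class II genes had a median of -0.13 (percentile 0.09), with 8 of 9 members below 0, including H2-DMa (-0.30) and Ciita (-0.20). Immediate early and heat shock genes had a median of -0.13 (percentile 0.27), with Nr4a1 at -0.31 and Egr1 at -0.30. The unfolded protein response list was at 0.07 (percentile 99.5) and the M2 marker list at 0.08 (percentile 99.98), but only 10 of the 24 M2 markers reached the floor on an M1 array. The dendritic cell list was at -0.16 (percentile 0.68). The remaining lists with a percentile lay inside the band that holds 95% of random lists, with medians from -0.05 to 0.09.

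The same treatment was then examined in M2 macrophages. Of 10284 genes, 36 were at least 2-fold higher with IL-1α and 0 were 2-fold lower, and at 1.5-fold the numbers were 90 and 0. The largest difference was in Acod1, which makes the immunometabolite itaconate (3.90, 14.9-fold), followed by the neutrophil chemokine Cxcl2 (9.1-fold), the C-type lectin Clec4e (8.3-fold), Il1b (5.9-fold), the fatty acid receptor Gpr84 (5.1-fold), Ptgs2 (4.7-fold), Gbp5 (4.3-fold), H2-M2 (4.1-fold), Il1a (3.9-fold) and Ifi205 (3.7-fold). Of these 10 genes, 9 read under the floor in M2 with vehicle, as did 18 of the 36, so their folds and order rest on baselines not shown to be above background. The lowest gene under the naming rule, the histone H3c4, was at -0.49. The largest difference of any gene in the M1 pair, in either direction, was 0.847, and 43 genes exceeded it in the M2 pair, all upward.

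NF-κB targets had the largest list median in M2, 0.73. Of 24 members, 8 were at least 2-fold higher, 0 were lower and 23 were above 0, with Nfkbie at 1.82, Vcam1 at 1.74 and the inhibitor Nfkbia at 1.65. Of 18 chemokines at the floor, 6 were at least 2-fold higher, including Cxcl2, Ccl17 (3.7-fold), Ccl22 (3.2-fold) and Cxcl10 (3.1-fold), while Ccl2 (0.10) and Cxcl1 (0.03) were close to their vehicle levels. Of 11 cytokine genes, 3 were at least 2-fold higher (Il1b, Il1a and Tnf at 3.7-fold). Il6 was under the floor on both M2 arrays. The IL-1 family list had a median of 0.18, with the inflammasome sensor Nlrp3 at 1.00 (just under 2-fold before rounding) and the co-receptor Il1rap at 0.44, whereas the receptor antagonist Il1rn was at 0.09. Interferon-γ response genes, of which 16 of 22 reached the floor on an M2 array, had a median of 0.24 (Cd40 1.35, Socs3 0.78) and type I interferon-stimulated genes of 0.20, with Ifit3 at 1.21, Ifit1 at 1.14 and Cmpk2 at 0.82. Vcam1, Cxcl10, Nlrp3, Socs3, Ifit3 and Ifit1 read under the floor in M2 with vehicle. The medians of these 6 lists lay above every random list. Random lists were matched on the mean of the 4 arrays. Members far lower in M2, such as Gbp5 (12.47 in M1 and 5.73 in M2 with vehicle), were therefore not matched on their M2 level. All-gene differences in M2 had a median of 0.05, which the random lists share.

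The M2 marker list did not stand apart with IL-1α in M2 (median 0.06, percentile 48.4). Retnla (-0.03), Arg1 (-0.06), Chil3 (-0.11) and Mrc1 (-0.04) differed little from M2 vehicle, and 2 of 24 markers were at least 2-fold higher, the chemokines Ccl17 and Ccl22. Eicosanoid genes had a median of 0.17 (percentile 99.9; Ptger4 0.85, Pla2g4a 0.59) and antioxidant and iron genes of 0.08 (percentile 98.4; Slc7a11 0.62). The macrophage core list was at -0.03 (percentile 1.09). The other lists with a percentile lay inside the 95% band of random lists, among them cholesterol synthesis (0.12), cell cycle (0.08), pattern recognition receptors (0.09, with Clec4e at 3.06 and Tlr2 at 0.83), lipid handling (0.01, with the oxidised lipoprotein receptor Olr1 at 1.76) and neutrophil markers (-0.09).

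The difference of the responses, M2 minus M1, is the contrast named in the study design. In 34 of 10625 genes it was at least 1 and in 0 at most -1. Of the 34, 30 were among the 36 genes 2-fold higher in M2. That overlap follows largely from the contrast, since no gene at the floor reached 2-fold in M1. The difference of responses was 3.89 for Acod1, 3.05 for Cxcl2, 2.90 for Clec4e, 2.42 for Gpr84, 2.30 for Il1b, 2.21 for Ptgs2, 1.95 for Ccl17 and 1.72 for Tnf. The most negative named genes were Enpp4 (-0.85), Fzd9 (-0.77) and Cd300e (-0.71). The first 6 of these genes read under the floor in M2 with vehicle, Ccl17 on both M1 arrays, and Enpp4 and Cd300e on both M2 arrays, so their sizes and order are uncertain. In M1, Acod1, Clec4e, Ptgs2 and Tnf read within 2 log2 units of the top of the vehicle array (14.4), which limits what their differences show. The NF-κB list had a median difference of 0.72, with 23 of 24 members larger in M2. The chemokine list was at 0.25, the cytokine list at 0.24, the type I interferon list at 0.26 and the interferon-γ list at 0.23, each at percentile 99.9 or above, as was the IL-1 family list at 0.21. The immediate early and heat shock list was at 0.20 (percentile 98.7). The macrophage core list lay outside the 95% band in the other direction, at -0.05 (percentile 0.12), with 8 of 12 members below 0. The other lists with a percentile lay inside the band. The 4 arrays leave no degree of freedom for a test of this contrast.

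**Figure D2:**
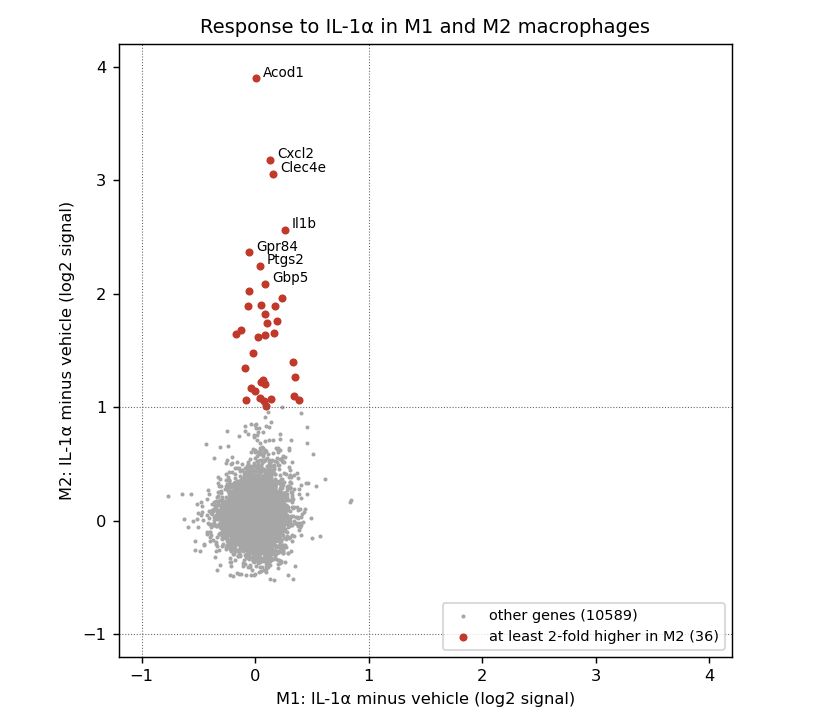
Log2 difference between IL-1α and vehicle for each of 10625 genes in M1 (horizontal) and in M2 (vertical); red points are the 36 genes at least 2-fold higher in M2, and dotted lines mark 2-fold. All 36 lie between -0.17 and 0.39 on the M1 axis.

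Across genes, which are not independent replicates, the 2 responses had a Pearson r of 0.09 and a Spearman rho of 0.07, on arrays that the responses do not share. Without a floor, r was -0.02, and with the floor at the 75th percentile it was 0.17. At 1.5-fold, 3 genes were higher in M1 and 99 in M2 among the 10625, and 0 were in both (0.03 by chance). In the limma additive model, no gene passed the threshold for an IL-1α effect common to both phenotypes, and with the floor at the 75th percentile 1 gene, Malt1, did. At an unadjusted p under 0.05 there were 646 genes, where 531 would be so by chance, and the smallest limma adjusted p was 0.069, for Malt1 (0.57 ± 0.07 SE). Adjusted over the list alone, 22 of 24 NF-κB targets, 10 of 20 chemokines, 7 of 21 type I interferon-stimulated genes and 3 of 14 cytokines passed in limma, all upward, against 0 in each list over all genes. So did 4 IL-1 family genes, 4 pattern recognition receptors, 2 genes each of the matrix, eicosanoid and antioxidant lists, and the stromal marker Acta2. These passes do not show an effect in each phenotype. The 10 chemokines had a median of 0.02 in M1, with 5 below 0, and of 1.35 in M2. The 22 NF-κB targets had 0.12 in M1, with 20 above 0, and 0.79 in M2, and the 7 interferon-stimulated genes 0.04 and 0.81.

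With IL-1α on both sides, M2 differed from M1 by at least 2-fold upward in 854 and downward in 635 of 10479 genes. Rnase2a (8.49), Retnla (7.63) and Arg1 (5.86) were again higher in M2, and Gbp4 (-7.45), Cxcl9 (-6.83) and Nos2 (-5.89) higher in M1, and on the lower of the IL-1α arrays each of these 6 read under the floor, so these sizes are uncertain as well. The NF-κB list median was -0.91 under IL-1α, against -1.46 under vehicle, and that of the type I interferon list -3.72 against -3.99. Il1b read 9.41 in M2 with IL-1α and 11.73 in M1 with vehicle, and Acod1 11.35 and 13.75. Of the 36 genes, 24 were higher in M1 with vehicle than in M2 with IL-1α. The other 12 included Cxcl2, Ccl17, Ccl22, Olr1 and Edn1, the last named after its value was seen, and Ccl17 read 10.80 in M2 with IL-1α, 8.91 in M2 with vehicle and 7.20 in M1 with vehicle.

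**Figure D3:**
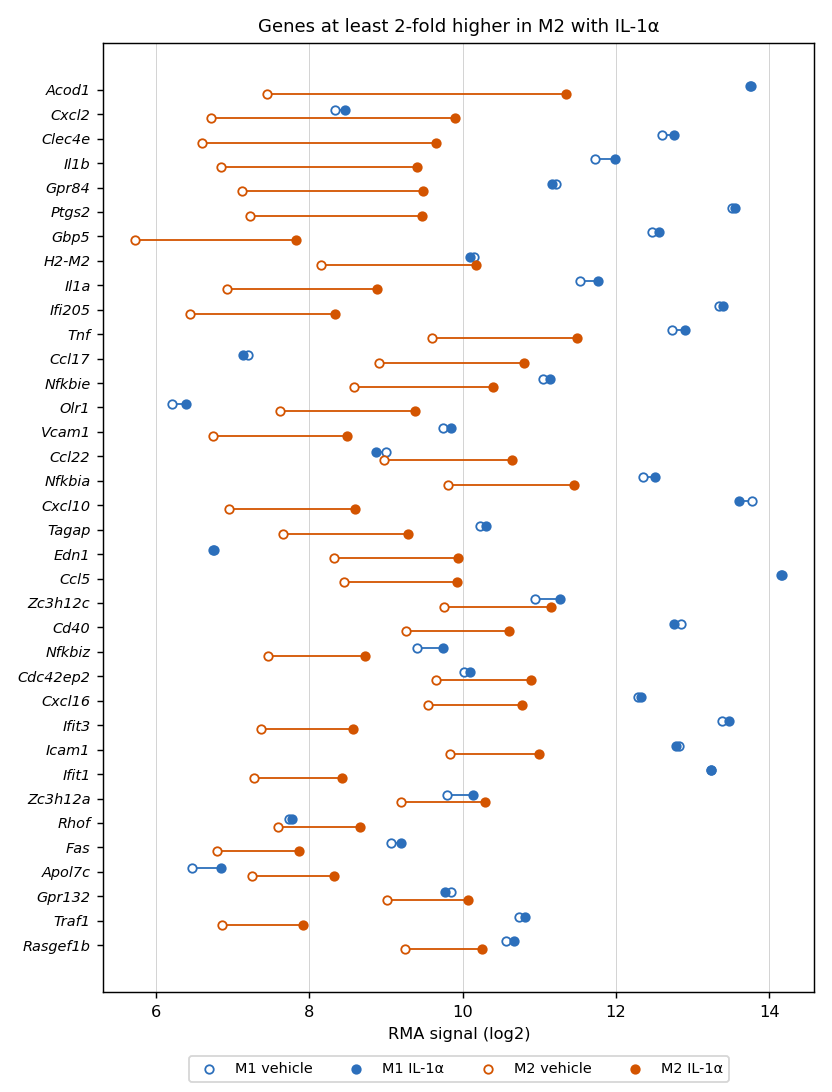
RMA log2 signals of the 36 genes at least 2-fold higher in M2 with IL-1α, with 1 array per point (blue M1, orange M2; open vehicle, filled IL-1α; lines join the arrays of a phenotype). The M1 points of each gene lie within 0.39 of each other, and 24 genes read higher in M1 with vehicle than in M2 with IL-1α.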

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

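The tests of technical explanations, the 1.2-fold limit for opposite directions and the 2 log2 units of room under the array's top were chosen after the results had been seen, and the test of mixed RNA was changed more than once after its outcome was known. With 1 array per group, no group was searched for a sample far from the others.

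The genes at least 2-fold higher in M2 with IL-1α differed little between the M1 arrays. The values argue against a signal ceiling for 24 of the 36 genes, which read at least 2 log2 units under the top of the M1 vehicle array (14.4) and had a median difference of 0.093 in M1 (from -0.12 to 0.39) and 1.63 in M2. Among the 24, Ccl17, Olr1, Edn1 and Apol7c (the highest, 0.39) read under the floor on both M1 arrays, so their M1 differences are uncertain. For the other 12 genes, nearer the top, a ceiling cannot be told apart from an absent response. A single vehicle RNA on both M1 arrays cannot be decided on. Of the 36 genes, 27 were above 0 in M1 and their median lay at percentile 99.99 of random lists. That percentile is not a test across samples. In the same pair the M2 marker list lay at 99.98, with only 10 of 24 members at the floor on an M1 array. An M1 culture that received no IL-1α cannot be told apart, since there is no second M1 vehicle culture to set the median of 0.081 against, and a difference between the phenotypes stays open and untested.

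Of the interferon-γ and type I interferon lists, Cxcl10, Gbp5, Cd40, Ifit1 and Ifit3 were at least 2-fold higher in M2 with IL-1α. Their median was 1.35, and at least 1.292 after loess centring and quantile normalisation. The deposited values were already normalised, so these steps could change little: the all-gene M2 median went from 0.053 to 0.036 and 0.008. The rise is thus not a shift shared by all genes, but the scaling before deposit was not tested. M1 RNA mixed into the M2 IL-1α sample would need a share of 1.89% to 13.92% across the 5 genes. It was highest for Cd40, which alone read at the floor in M2 vehicle. No single share would therefore give all 5 rises as measured. The median share was about 2.04%, an uncertain value, since 4 of the 5 genes read under the floor in M2 vehicle. Of 62 other genes at least 16-fold higher in M1 than M2 under vehicle, a first test found 25 (40.3%) reaching 0.5 of the rise this share predicts, which decided nothing, and a second, with limits set after these values were seen, found 51.61% short of it by more than 3 SD, but 46 of the 62 read under the floor in M2 vehicle. Restricted to the 16 genes at the floor, with the limits of the second test, 3 fell short (18.75%: Irf7 with 0.42 against 1.05 predicted, Ms4a6b 0.17 against 0.67, Oas3 -0.12 against 0.65), which lies between those limits. This last form had little power, because 3 SD (SD 0.13) came close to the predicted rise of several of the 16. A gene with almost no rise could pass, as Gpr31b did with 0.05 against 0.43 predicted. The 16 also held Ccl5, itself 1 of the 36 genes at least 2-fold higher in M2 with IL-1α. Mixing as a source of part of these rises therefore cannot be told apart from a response of M2 cells. A response through secreted interferon is an untested hypothesis.

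With IL-1α, 6 genes differed by at least 1.2-fold in opposite directions in M1 and M2, and 26 in the same direction, where 10.0 and 6.77 would do so if the responses were independent. They were Fzd9 (0.29 in M1, -0.48 in M2), Kcns3 (0.29, -0.29), Lrp4 (0.26, -0.37), Praf2 (-0.30, 0.30), Slamf1 (-0.30, 0.65) and the predicted gene Gm13375 (-0.31, 0.30), and these differences between phenotypes were not tested. Among array features without a listed gene, which the comparisons did not use, 7 were at least 2-fold higher and 5 lower in M2 with IL-1α, against 3 and 4 in M1. These were 0.275% of 4356 features at the floor in M2 and 0.149% of 4702 in M1. Their difference of responses, M2 minus M1, was at least 1 in 12 and at most -1 in 35 of 4903. Each value is a single feature without a replicate, so these counts cannot be told apart from noise.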

How the results depend on the processing

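The robust eBayes fit was the 1 alternative chosen after seeing the data. Of the 93 alternative values of the counts and of the correlation, 75 stayed within 1.5 times their main value or within its interval over genes. At 1.5-fold the counts were 1477 higher and 1400 lower for M2 against M1 under vehicle, 2 and 4 for IL-1α in M1, 90 higher in M2, 108 higher and 15 lower for the difference of responses, and 1740 and 1197 for M2 against M1 under IL-1α. With the floor at the 75th percentile, which tests fewer genes, they were 429 higher and 559 lower for M2 against M1 under vehicle (737 and 716 at the main floor), 19 higher for IL-1α in M2 (36), 533 higher under IL-1α (854) and 2230 higher for the phenotype effect (3526). The correlation of responses was 0.1671 there, and Malt1 became the 1 gene past the limma threshold for a common IL-1α effect. Without a floor, 1 gene was lower in M1 with IL-1α, 4 were lower in the difference of responses, the correlation turned to -0.0189 and the dendritic cell median to 0.215; these settings add dim genes, and the cause was not tested. Loess centring, like the higher floor, gave more genes lower than higher for M2 against M1 under vehicle (723 higher, 737 lower). Loess centring, quantile normalisation, the brightest probe set, eBayes without the trend and the robust fit moved no count past 1.5 times. Over lists, 516 of 610 alternative medians moved by less than the spread of random lists and 93 by more, with 1 reversal, that of the dendritic cell list. Of the named genes' values, 1457 of 1470 moved by less than the spread of the M1 pair. No paired analysis was possible because each group holds 1 array, so there are no replicate pairs to block on (the additive model's blocks are the phenotypes), and no replicate could be left out for the same reason. On simulated data, the 2-fold rule found 32 of 67 genes that truly changed 2-fold in M2. That change equals the threshold of the rule, so noise decided which of them passed, and the share is no measure of sensitivity.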

Other observations

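Of the 36 genes at least 2-fold higher in M2 with IL-1α, 13 were on none of the fixed lists. Besides Acod1, Gpr84, H2-M2 and Ifi205, they included, chosen for mention after their values were seen, the vasoactive peptide gene Edn1 (1.62 in M2, 0.03 in M1), Tagap (1.63 and 0.09), Zc3h12c (1.40 and 0.33), the death receptor Fas (1.07 and 0.14) and Apol7c (1.06 and 0.39). In 4 of the 36 genes, Ccl17, Olr1, Edn1 and Apol7c, M1 vehicle read lower than M2 vehicle, while 27 read at least 2-fold higher in M1 vehicle. Those 4 genes read under the floor on both M1 arrays, so their M1 values are uncertain. Another 54 genes were between 1.5-fold and 2-fold higher in M2.

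The lowest genes in M2 with IL-1α included the histones H3c4 (-0.49) and H2bc8 (-0.48) and the transcription factor Klf2 (-0.45), all under 2-fold. In M1, the metallothioneins Mt2 (-0.38) and Mt1 (-0.33) and the cell cycle genes Tk1 (-0.29), Rrm2 (-0.26) and Mcm7 (-0.26) had negative differences, and the cell cycle list median of -0.05 lay at percentile 2.61, with 15 of its 24 members at the floor on an M1 array. Tk1 and Rrm2 read close to the floor in M1 with vehicle (7.70 and 7.84) and under it with IL-1α (7.41 and 7.58), so their differences are uncertain.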
